A study of Arabidopsis thaliana with 8 samples.

How the data were processed

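RNA of rosettes from 28-day-old untreated Arabidopsis thaliana plants of the Col-0 ecotype was sequenced in 8 libraries, 2 for each of 4 genotypes. The genotypes were wild type (WT), a pbl19 mutant carrying PBL19C3A-GFP-HA under the PBL19 promoter (the PBL19C3A line), and further lines with this construct in pbl19. These also carry a mutation in sid2 (the sid2 line) or in eds1 (the eds1 line). The titles name the construct, but not whether its insertion is the same in these lines. PBL19 is a receptor-like cytoplasmic kinase, and PBL19C3A is the form whose palmitoylation site is mutated. SID2 is the isochorismate synthase ICS1, which makes most of the salicylic acid of immune leaves, and EDS1 is a lipase-like regulator of immune signalling. Per the labels, total RNA was extracted with RNAiso Plus and libraries followed standard Illumina protocols. Whether the libraries keep the strand of a read, and which tool counted the reads, is not given in the sources used here, so reads of overlapping or near-identical genes could not be separated.

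The deposited tables hold whole-number read counts per gene and library, and FPKM values per gene and library made by the authors, per the file headers. HISAT2 2.0.4 and the TAIR10 build are named in the submitters' processing notes. There were 3 count tables, each holding the WT libraries beside those of 1 transgenic line, and 4 further FPKM tables with 1 genotype each. All 571826 values of these files were compared with the joined values, and 0 differed. The counts of each transgenic line stand in only 1 file, so for them this is no check. The tables listed 18048 genes for WT and the PBL19C3A line, 17991 for WT and the sid2 line, and 17534 for WT and the eds1 line. Of the 18333 genes in any table, 17327 stood in all 3, and 213 were loci outside the reference annotation, named newGene in the files. In each table, every gene reached at least 1 CPM (counts scaled to the library total) in at least 2 of its 4 libraries. All 16950 genes at 1 CPM or more in both WT libraries were in every table. A gene absent from a table was therefore low in that line and in WT, and it was given no value there. Locus identifiers were matched to names in the reference annotation of the TAIR10.1 assembly for 17985 genes. Because the labels name another release, no coordinates are given, and that annotation served for names and neighbour order alone. All measurement columns were matched to a sample by name.

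Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM scaling (one factor per library from the bulk of genes), the filterByExpr low-count filter and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. The filter removed no gene, since the tables had been restricted already. The design fixed before the data were examined was 1 fit of all 8 libraries with genotype as the only term. Because each table lists its own genes, a gene was fitted with every library that has a value for it, which is 8, 6 or 4 libraries, and the adjustment ran over all genes of a comparison. This split of the fit was set after the tables were seen. There were 6 comparisons. Log2 fold changes are given with their standard errors, and levels as the authors' FPKM, as mean ± SD over the 2 libraries of a genotype. The biological coefficient of variation was 18.1%. On counts simulated for the PBL19C3A line against WT over 18063 genes, this test recovered 60% of 100 genes changed 2-fold. It recovered 100% of 100 genes changed 4-fold, with 9 calls among unchanged genes. The changed genes were drawn from those above a level limit, and all genes had the same variation. These shares therefore do not cover low genes or genes that vary more.

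The comparisons, the tests, the alternatives, the rule for naming genes and 20 gene lists were fixed before the data were examined. The lists hold 225 genes, of which 208 stood in at least 1 table. The named genes of each comparison are PBL19, ICS1 and EDS1, then up to 4 members per list with the largest absolute log2 fold change past the threshold. To these come the 5 highest and 5 lowest changes among genes of at least 10 FPKM in the higher group with the same direction in every pair of libraries. In the comparison of the eds1 line with WT every called gene was listed. The lists cover salicylic acid synthesis and turnover, salicylic acid response, N-hydroxypipecolic acid, the EDS1 hub with intracellular receptors, pattern-triggered immunity, camalexin with indole glucosinolates, jasmonate with ethylene, photosynthesis, endoplasmic reticulum folding, senescence, cell expansion, cell cycle, heat shock, abscisic acid, the clock, flowering, root, guard cell with epidermis and phloem, and reference genes, besides PBL19, ICS1, EDS1 and EDS1B. The 17 lists with enough genes in all 3 tables were tested with camera of limma 3.58.1 at its preset correlation of 0.01, over genes in all 3 tables, with adjustment over the 102 pairs of a list and a comparison. ICS1 also belongs to the salicylic acid synthesis list, and EDS1 and EDS1B to the EDS1 hub list, so mutated genes count among the members. Camera with an estimated correlation and fry were run beside the preset. None of the camera calls held with an estimated correlation, which called 0 pairs where the preset called 62, although 33 had an unadjusted p under 0.05. For salicylic acid synthesis in the PBL19C3A line against WT, the estimated correlation was -0.0204, below the preset. Its camera adjusted p still went from 2.21e-07 to 0.0942, so correlated genes cannot account for that loss. With 2 libraries per genotype this version has little power, and its 0 calls cannot decide against a list. Fry, which asks whether a list moves one way without setting it against other genes, called 53, and its mixed test, which asks for change in either direction, called 68. For 9 pairs the median, the mean and the direction of camera differed in sign, and camera called none of these. They were N-hydroxypipecolic acid, heat shock and reference genes in the sid2 against the PBL19C3A line, heat shock in the eds1 against the PBL19C3A line and against the sid2 line, abscisic acid in the sid2 line against WT, and salicylic acid synthesis, cell expansion and clock in the eds1 line against WT.

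A fold change against a group with 0 counts is given as a lower bound, against a floor of 3 counts over the group. Against 1 to 3 counts it is given as a ratio with its 95% counting interval. These bounds and intervals cover counting error only. The share of the change of the PBL19C3A line that was lost in the other lines was described as the percent of its called genes within 2-fold of WT, and as the slope of a line's log2 change against WT on that of the PBL19C3A line, over genes with more than 3 counts in each group. Unchanged groups were simulated 100 times against the same WT libraries to give the value that shared controls produce with no effect, and 50 further simulations over 17327 genes were tested with edgeR for the calls they share. In 20 more, the PBL19C3A line kept its changes, those of the sid2 line went to random genes within 20 bins of WT level, and the eds1 line equalled WT.

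Alternatives were DESeq2 1.42.0 size factors in place of TMM, the DESeq2 Wald test, no low-count filter, genes of at least 5 FPKM in a genotype, a minimum of 2-fold, a fit of only the 2 groups compared, the replicate number as a block, and fits without each library in turn. A fit of only genes in all 3 tables, a list test that ranks all genes of a comparison, and the share lost among calls of at least 2-fold were chosen after seeing the data. Libraries with the same number were checked for shared deviations. The difference between libraries 1 and 2 correlated across 17327 genes in each of the 6 pairs of genotypes, between 0.134 and 0.345, so the numbers were treated as pairing the libraries. This pairing comes from the data, as the labels name no day or batch, and the fit without the block, fixed before, was kept. In fits that leave a genotype with 1 library, that library is assumed to vary like the others. The titles number 2 libraries per genotype, while the design text of the series speaks of one biological replicate, so p-values measure only the spread between these libraries, which may be technical. The 2 libraries of a genotype differed by far more than sampling noise, with a chi-square per gene between 35.4 and 63.5 over at least 17315 genes. Repeat sequencing of 1 library would leave sampling noise alone, so these values argue against it. Separate libraries of the same plants stay open.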

Results

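Read counts per gene were collected from rosettes of 28-day-old untreated Arabidopsis plants, in 2 libraries for each of 4 genotypes. Wild type (WT) is Col-0. The PBL19C3A line is a pbl19 mutant that carries PBL19C3A-GFP-HA under the PBL19 promoter, with the palmitoylation site of the kinase mutated, and its labels give constitutive immunity as the phenotype. The sid2 line is the sid2 PBL19C3A line, which carries a mutation in sid2, the gene of the isochorismate synthase ICS1, per the labels, and whose labels also give constitutive immunity. The eds1 line is the eds1 PBL19C3A line, which carries a mutation in eds1, the gene of the immune regulator EDS1, per the labels, and whose labels give a phenotype like WT. In libraries 1 and 2, the total counts were 46433816 and 46560720 for WT, 46473863 and 37373977 for the PBL19C3A line, 51202472 and 47994640 for the sid2 line, and 48470650 and 46840480 for the eds1 line. Across genes, the first principal component held 66.6% of the variance. It placed WT at -57.8 and -45.8 and the eds1 line at -40.8 and -56.9, with the sid2 line at 39.7 and 29.7 and the PBL19C3A line at 69.8 and 62.2. Levels are given as mean ± SD of FPKM over n = 2 libraries, and log2 fold changes with their standard error. Bounds and intervals for genes at 0 to 3 counts cover counting error only, and p-values measure only the spread between the numbered libraries, which may be technical.

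The genes named by the genotypes were examined first in every library. PBL19 (AT5G47070), the kinase whose mutated form is expressed from the transgene, stood at 8.90 ± 2.13 FPKM in WT, 1917 ± 396 in the PBL19C3A line, 791 ± 233 in the sid2 line and 51.5 ± 19.2 in the eds1 line. Reads of the transgene and of the native gene could not be separated. ICS1 (AT1G74710), which makes the precursor of salicylic acid, stood at 7.30 ± 2.11 in WT and 64.9 ± 10.9 in the PBL19C3A line, against 4.73 ± 0.406 in the sid2 line and 7.13 ± 1.07 in the eds1 line. EDS1 (AT3G48090) stood at 10.7 ± 3.78 in WT, 57.1 ± 1.93 in the PBL19C3A line, 29.1 ± 6.78 in the sid2 line and 4.1 ± 1.26 in the eds1 line. Reads of the mutated genes were still counted, 553 and 454 of ICS1 in libraries 1 and 2 of the sid2 line and 539 and 331 of EDS1 in those of the eds1 line, so counts alone do not show what the mutations remove. The near-identical neighbour of EDS1, EDS1B (AT3G48080), whose reads may be confused with those of EDS1, stood at 0.497 ± 0.369 in WT, 31.9 ± 2.43 in the PBL19C3A line and 4.30 ± 0.0479 in the sid2 line, and the table of the eds1 line lists no value for it.

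**Figure D1:**
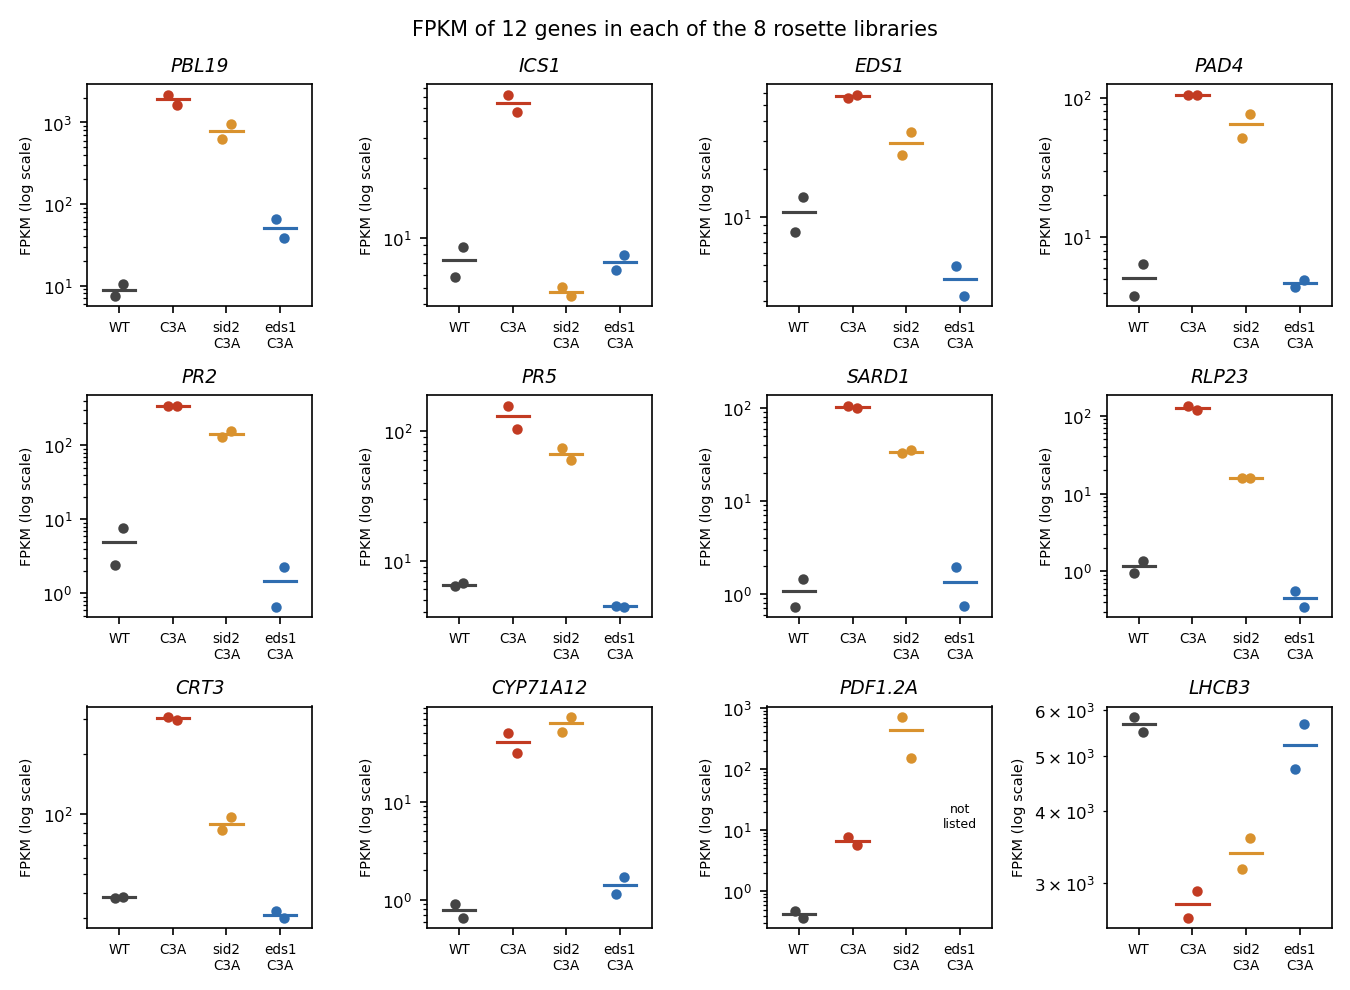
FPKM on a log axis for 12 genes in the 4 genotypes, with a dot per library and a line at the mean of 2 libraries. PBL19 lies at 1917 ± 396 FPKM in the PBL19C3A line and at 51.5 ± 19.2 in the eds1 line, and "not listed" marks a gene without a value.

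The first question was what the PBL19C3A transgene line expresses differently from WT. Among measured genes, 16 of 16 of the salicylic acid response, 14 of 14 of the EDS1 hub and intracellular receptors and 13 of 15 of camalexin and indole glucosinolate synthesis rose, while 21 of 22 of photosynthesis and 5 of 6 of cell expansion fell. Camera called 8 lists higher and 3 lower, and 0 with an estimated correlation (adjusted p from 0.0942 to 0.348). The pathogenesis-related gene PR1 (AT2G14610), a marker of salicylic acid responses, went from 0.884 ± 0.33 to 2068 ± 1161 FPKM, a log2 rise of 11.12 ± 0.62 (edgeR quasi-likelihood adjusted p = 0.000113). PBL19 itself rose by 7.71 ± 0.42 (edgeR adjusted p = 6.51e-05), ICS1 by 3.12 ± 0.24 (edgeR adjusted p = 0.000186) and EDS1 by 2.38 ± 0.29 (edgeR adjusted p = 0.00115).

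Of the 13 measured genes of salicylic acid synthesis and turnover, 9 rose, 1 fell and 3 did not pass the test, with 9 and 1 adjusted over the list alone (camera adjusted p = 2.21e-07, adjusted p = 0.0942 with an estimated correlation). The salicylate hydroxylase gene DLO1 (AT4G10500) rose by 9.19 ± 0.45, the transcription factor gene SARD1 (AT1G73805) by 6.52 ± 0.47 and PBS3 (AT5G13320), which conjugates isochorismate to glutamate, by 5.28 ± 0.36. All 16 measured genes of the salicylic acid response rose, and all 16 adjusted over the list alone (camera adjusted p = 2.61e-10, adjusted p = 0.109 with an estimated correlation). Among them, WRKY38 (AT5G22570) was at least 647-fold higher and the glutaredoxin gene GRX480 (AT1G28480) at least 281-fold higher, as both had 0 counts in WT. For N-hydroxypipecolic acid, the mobile signal of systemic resistance, 6 of 8 genes rose and 2 did not pass the test, with 6 adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.141 with an estimated correlation). FMO1 (AT1G19250), which makes that signal, rose by 10.78 ± 0.79, from only 0 and 5 counts in WT libraries 1 and 2. The aminotransferase gene ALD1 (AT2G13810) rose by 6.65 ± 0.68 (5.64 to 12.86 over the fits without 1 library). The reductase gene SARD4 (AT5G52810) rose by 3.87 ± 0.22. All 14 measured genes of the EDS1 hub and of intracellular immune receptors rose, and all 14 adjusted over the list alone (camera adjusted p = 5.12e-12, adjusted p = 0.141 with an estimated correlation). The EDS1 partners PAD4 (AT3G52430) and SAG101 (AT5G14930) rose by 4.31 ± 0.30 and 2.26 ± 0.17.

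Of 21 genes of pattern-triggered immunity, 15 rose and 6 did not pass the test, with 16 adjusted over the list alone (camera adjusted p = 3.14e-09, adjusted p = 0.228 with an estimated correlation). The receptor gene RLP23 (AT2G32680) rose by 6.73 ± 0.26, from 1.16 ± 0.305 to 127 ± 11.8 FPKM, NHL10 (AT2G35980) by 6.45 ± 0.60, the kinase gene MPK11 (AT1G01560) by 6.22 ± 0.82 (5.28 to 9.52 over the fits without 1 library) and FRK1 (AT2G19190) by 4.89 ± 0.31. Of 15 genes of camalexin and indole glucosinolate synthesis, 13 rose, 1 fell and 1 did not pass the test, with the counts of 13 and 1 adjusted over the list alone (camera adjusted p = 1.15e-07, adjusted p = 0.141 with an estimated correlation). The cytochrome P450 genes CYP71A12 (AT2G30750) and CYP71A13 (AT2G30770) rose by 5.65 ± 0.38 and 5.95 ± 0.57, and the regulator gene MYB122 (AT1G74080) by 6.74 ± 1.03 (5.75 to 11.14 over the fits without 1 library). The 17 jasmonate and ethylene genes were mixed, with 8 higher, 1 lower and 8 not past the test, and 8 higher and 2 lower adjusted over the list alone. Camera made no call for them (adjusted p = 0.312). There the ethylene response factor gene ERF1 (AT3G23240) rose by 4.37 ± 0.46 and the hevein-like gene HEL (AT3G04720) by 2.97 ± 0.20. All 11 measured genes of protein folding in the endoplasmic reticulum rose, and all 11 adjusted over the list alone (camera adjusted p = 1.87e-14, adjusted p = 0.0942 with an estimated correlation). The chaperone gene BIP3 (AT1G09080) rose by 3.67 ± 0.46, the calreticulin gene CRT3 (AT1G08450) by 2.96 ± 0.12 and the disulfide isomerase gene PDIL1-2 (AT1G77510) by 1.98 ± 0.15. In leaf senescence, 6 of 8 genes rose and 2 did not pass the test, with 6 adjusted over the list alone (camera adjusted p = 0.000599, adjusted p = 0.268 with an estimated correlation), led by SAG13 (AT2G29350) with 7.24 ± 0.75 and WRKY6 (AT1G62300) with 3.11 ± 0.21.

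Of 22 photosynthesis genes, 21 fell and 1 did not pass the test, with 21 adjusted over the list alone (camera adjusted p = 3.14e-09, adjusted p = 0.348 with an estimated correlation). The light-harvesting genes LHCB3 (AT5G54270), LHCB2.2 (AT2G05070) and LHCB2.1 (AT2G05100) fell by 1.08 ± 0.15, 0.98 ± 0.15 and 0.94 ± 0.13. Of 6 expansin and other cell expansion genes, 5 fell and 1 did not pass the test, with 5 adjusted over the list alone (camera adjusted p = 0.00064, adjusted p = 0.141 with an estimated correlation). The expansin genes EXPA5 (AT3G29030), EXPA3 (AT2G37640) and EXPA11 (AT1G20190) fell by 1.72 ± 0.32, 1.27 ± 0.16 and 1.14 ± 0.16. Of 7 markers of guard cells, epidermis and phloem, 6 fell and 1 did not pass the test, with 6 adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.236 with an estimated correlation), and the guard cell channel gene KAT1 (AT5G46240) fell by 1.87 ± 0.22. The abscisic acid and drought list split, with 2 genes higher, 4 lower and 1 not past the test, and the same numbers adjusted over the list alone. Its cold-induced gene COR15A (AT2G42540) fell by 3.28 ± 0.55. In heat shock 2 of 7 genes rose, among them HSP90.1 (AT5G52640) by 1.99 ± 0.34, and among 9 clock genes 1 rose, TOC1 (AT5G61380) by 1.5 ± 0.27. The counts adjusted over the list alone were again 2 and 1. Camera made no call for the abscisic acid, heat shock and clock lists (adjusted p = 0.0528, 0.214 and 0.849), but with the replicate block it placed the abscisic acid list lower (adjusted p = 0.0437). Of 3 measured flowering markers, 1 fell and 2 did not pass the test, with 1 adjusted over the list alone, and of the 5 root markers 0 were measured. Among 8 reference genes 2 rose, with 2 adjusted over the list alone, and 6 did not pass the test. None of the 10 measured cell cycle genes passed the test in edgeR or in DESeq2 or adjusted over the list alone, and 1 had an unadjusted p under 0.05.

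Among genes outside the lists, the highest changes were in genes at 0 counts in WT. They included AT3G28510, at least 2322-fold higher, the cytochrome P450 gene CYP76C5 (AT1G33730), at least 891-fold higher, and AT1G33950, at least 623-fold higher. The lowest were the growth regulator gene PRE1 (AT5G39860), which fell by 3.83 ± 0.49, AT1G13650, which fell by 3.76 ± 0.77, the desaturase gene ADS1 (AT1G06080), by 2.89 ± 0.35, and the auxin-responsive gene SAUR22 (AT5G18050), by 2.88 ± 0.40. The call of AT1G13650 was lost without PBL19C3A library 1, at values from -4.59 to -3.21 over the fits without 1 library. In all, 6536 of 18048 genes changed, 3854 higher and 2682 lower, of which 2140 and 919 by at least 2-fold. The count was 4068 without WT library 1 and 3729 without PBL19C3A library 1. Of 67 named calls, 18 were lost without some single library, and 0 changed sign.

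**Figure D2:**
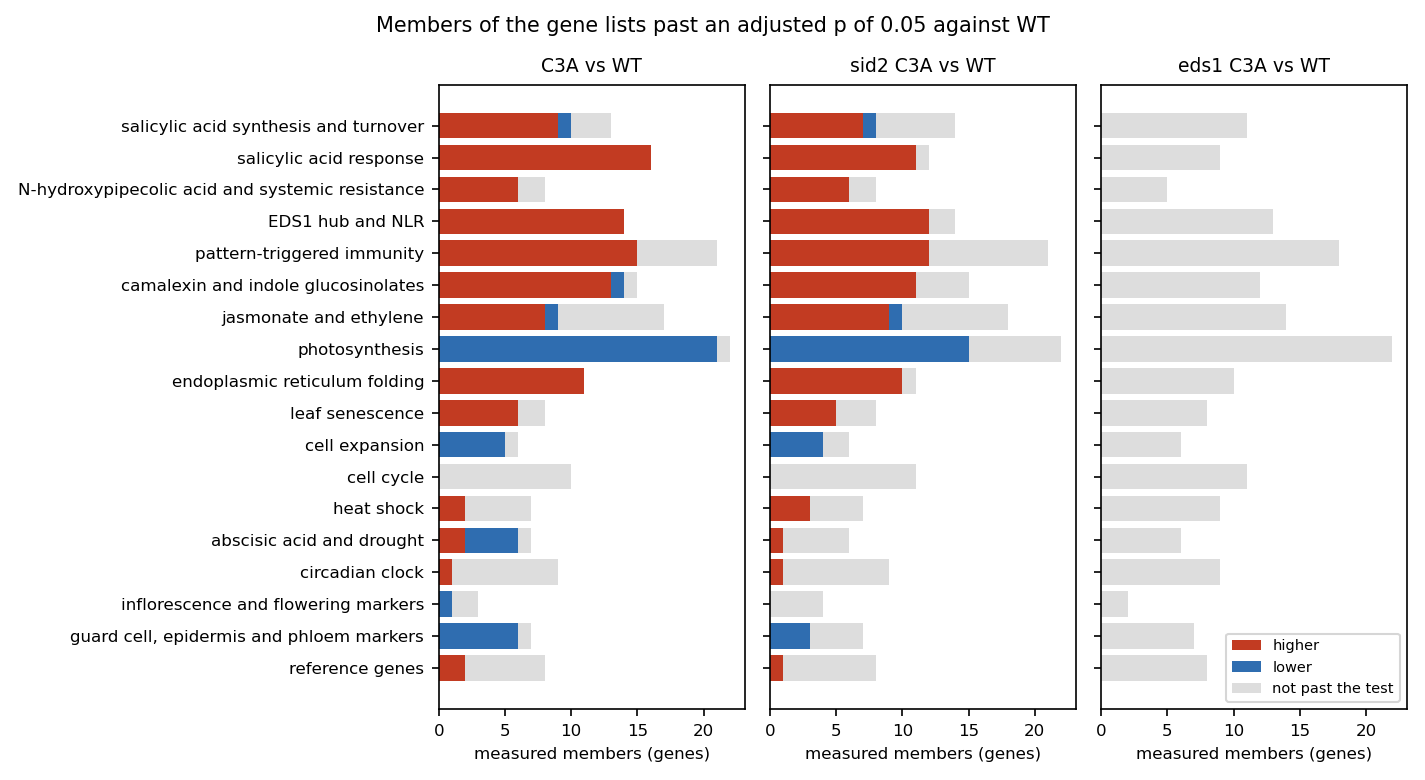
Number of measured members of 18 gene lists that were higher, lower or not past an adjusted p of 0.05 against WT, for the PBL19C3A, sid2 and eds1 lines. In the eds1 line 0 members of any list passed, where 21 of 22 photosynthesis genes were lower in the PBL19C3A line.

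The next question was how the sid2 line differs from the PBL19C3A line. Of the 12 salicylic acid response genes with a value in both lines, 4 were lower in the sid2 line than in the PBL19C3A line. So were 7 of 11 folding genes of the endoplasmic reticulum, while 2 defensin genes of the jasmonate and ethylene branch were higher. The other response genes that rose in the PBL19C3A line, among them WRKY38 and GRX480, have no value in the sid2 line. They were low there, so the count of 4 leaves out genes that may depend on SID2. ICS1 fell by 3.80 ± 0.24 (edgeR adjusted p = 0.00152), RLP23 by 3.03 ± 0.22 (edgeR adjusted p = 0.00253) and CRT3 by 1.77 ± 0.11 (edgeR adjusted p = 0.00136). PCR1 (AT1G14880) fell by 7.07 ± 0.47, from 806 ± 78.1 to 6.05 ± 0.701 FPKM, and AT3G28510 fell by 5.94 ± 0.26. PBL19 had a log2 difference of -1.29 ± 0.32 (edgeR adjusted p = 0.0845) and EDS1 one of -1.0 ± 0.28 (edgeR adjusted p = 0.119), neither past the edgeR test over all genes. In DESeq2, and in edgeR adjusted over PBL19, ICS1, EDS1 and EDS1B alone, all 4 of these genes were lower in the sid2 line.

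Of 12 measured salicylic acid response genes, 4 fell and 8 did not pass the test, while 8 fell adjusted over the list alone (camera adjusted p = 5.57e-07, adjusted p = 0.15 with an estimated correlation). PR1 fell by 5.23 ± 0.46, to 55.5 ± 12.2 FPKM, WRKY54 (AT2G40750) by 3.45 ± 0.51 and the NPR1-binding gene NIMIN2 (AT3G25882) by 2.89 ± 0.51. Of 13 genes of salicylic acid synthesis and turnover, 1 rose, 3 fell and 9 did not pass the test, with 1 and 5 adjusted over the list alone (camera adjusted p = 0.0031, adjusted p = 0.141 with an estimated correlation), and DLO1 fell by 3.02 ± 0.29. ICS1, the gene mutated in the sid2 line, is 1 of these 3. In the EDS1 hub, 3 of 14 genes fell, with 6 adjusted over the list alone (camera adjusted p = 3.98e-07, adjusted p = 0.255 with an estimated correlation), among them the helper receptor gene NRG1.2 (AT5G66910) by 1.09 ± 0.11 and SAG101 by 0.89 ± 0.16. In pattern-triggered immunity, 3 of 21 genes fell, with 5 adjusted over the list alone (camera adjusted p = 5.23e-05, adjusted p = 0.366 with an estimated correlation), and besides RLP23 these were FRK1, by 1.39 ± 0.25, and the chitin receptor gene CERK1 (AT3G21630), by 0.71 ± 0.11. Of 11 folding genes of the endoplasmic reticulum, 7 fell, with 9 adjusted over the list alone (camera adjusted p = 4.06e-14, adjusted p = 0.0942 with an estimated correlation), among them ERDJ3B (AT3G62600) by 0.84 ± 0.11 and SHD (AT4G24190) by 0.74 ± 0.10. Of 17 jasmonate and ethylene genes, 4 rose and 13 did not pass the test, with 9 adjusted over the list alone (camera adjusted p = 4.78e-09, adjusted p = 0.148 with an estimated correlation). The defensin genes PDF1.2A (AT5G44420) and PDF1.3 (AT2G26010) rose by 5.99 ± 0.77 and 5.93 ± 0.77, their regulator gene ORA59 (AT1G06160) by 1.74 ± 0.26 and the allene oxide synthase gene AOS (AT5G42650) by 1.25 ± 0.11. PDF1.2A varied widely in the sid2 line, at 441 ± 404 FPKM.

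None of the 22 photosynthesis genes passed edgeR or DESeq2 or rose adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05, while camera placed the list higher (camera adjusted p = 0.000794, adjusted p = 0.604 with an estimated correlation). The abscisic acid list had 0 calls among 6 genes in edgeR, with 4 higher at an unadjusted p under 0.05, 2 higher in DESeq2 and 1 adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.134 with an estimated correlation). The guard cell, epidermis and phloem markers had 0 calls among 7 genes in edgeR and in DESeq2, and adjusted over the list alone, with 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0147, adjusted p = 0.348 with an estimated correlation). Fry made no call for the photosynthesis, guard cell and pattern-triggered immunity lists (adjusted p = 0.187, 0.0729 and 0.152). Among 15 camalexin genes edgeR called 0, DESeq2 called 1 higher and 2 were higher at an unadjusted p under 0.05, with 0 adjusted over the list alone. CYP71A12 stood at 41.0 ± 13.8 FPKM in the PBL19C3A line and 62.9 ± 15.6 in the sid2 line. Among 8 genes of N-hydroxypipecolic acid edgeR called 0, but adjusted over the list alone 3 rose and 3 fell, the same numbers as at an unadjusted p under 0.05, and DESeq2 called 2 higher and 3 lower. FMO1 stood at 56.5 ± 31.3 FPKM in the PBL19C3A line and 186 ± 52.5 in the sid2 line. In the senescence, cell expansion, cell cycle, heat shock, clock, flowering and reference lists edgeR called 0 genes, also adjusted over each list alone. At an unadjusted p under 0.05 these lists held 0, 2, 0, 1, 2, 0 and 0 genes, all higher, and DESeq2 called 1 gene in them, of cell expansion.

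Of 17812 genes, 469 changed, 116 higher and 353 lower, with 71 and 193 by at least 2-fold. Without 1 library this count was 34 and 24 without libraries 1 and 2 of the PBL19C3A line, and 61 and 56 without those of the sid2 line. ICS1, RLP23, CRT3, PCR1 and AT3G28510 kept their calls without each library in turn, and the other 24 of 29 named calls were lost without at least 1 of these 4 libraries, with no change of sign. PR1, for one, was lost without library 1 or 2 of the sid2 line, at log2 values from -5.70 to -4.52 over the fits without 1 library, and PDF1.2A without library 1 or 2 of the PBL19C3A line, at 4.49 to 6.71. DESeq2 called 1378 genes, and 924 were called with the replicate block. A further 163 genes that had risen in the PBL19C3A line against WT had no value in the sid2 line.

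The eds1 line was compared with the PBL19C3A line in the same way. In the eds1 line, 8 of 9 salicylic acid response genes, 12 of 13 EDS1 hub genes, 10 of 18 pattern-triggered immunity genes and 8 of 12 camalexin genes were lower, and 17 of 22 photosynthesis and 5 of 6 cell expansion genes were higher. Camera called 8 lists lower and 4 higher, and 0 with an estimated correlation (adjusted p from 0.0942 to 0.414). PBL19 itself fell by 5.22 ± 0.37 (edgeR adjusted p = 0.000181), ICS1 by 3.19 ± 0.24 (edgeR adjusted p = 0.000221) and EDS1 by 3.80 ± 0.31 (edgeR adjusted p = 0.000326). The glucanase gene PR2 (AT3G57260) fell by 7.87 ± 0.76, from 342 ± 6.04 to 1.45 ± 1.14 FPKM, beside 4.99 ± 3.68 in WT.

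Of 11 measured genes of salicylic acid synthesis and turnover, 7 fell, 1 rose and 3 did not pass the test, with 7 and 1 adjusted over the list alone (camera adjusted p = 3.82e-08, adjusted p = 0.0942 with an estimated correlation). PBS3 fell by 6.81 ± 0.39, SARD1 by 6.26 ± 0.47 and the salicylic acid transporter gene EDS5 (AT4G39030) by 4.07 ± 0.27. Of 9 response genes 8 fell, and 8 adjusted over the list alone (camera adjusted p = 1.88e-10, adjusted p = 0.141 with an estimated correlation), among them PR5 (AT1G75040) by 4.88 ± 0.23 and WRKY70 (AT3G56400) by 3.69 ± 0.50. For N-hydroxypipecolic acid 3 of 5 genes fell, and 3 adjusted over the list alone (camera adjusted p = 0.000668, adjusted p = 0.128 with an estimated correlation), among them SARD4 by 4.37 ± 0.23 and LLP1 (AT5G03350) by 3.93 ± 0.72. In the EDS1 hub 12 of 13 genes fell, and 13 adjusted over the list alone (camera adjusted p = 2.83e-12, adjusted p = 0.15 with an estimated correlation), with PAD4 at -4.48 ± 0.30. EDS1, the gene mutated in the eds1 line, is 1 of these 12. Of 18 pattern-triggered immunity genes 10 fell, and 10 adjusted over the list alone (camera adjusted p = 4.22e-07, adjusted p = 0.268 with an estimated correlation), among them RLP23 by 8.11 ± 0.28 and the receptor kinase gene SOBIR1 (AT2G31880) by 3.06 ± 0.35. Of 12 camalexin and indole glucosinolate genes 8 fell, 1 rose and 3 did not pass the test, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.05e-07, adjusted p = 0.148 with an estimated correlation), and CYP71A12 fell by 4.83 ± 0.36. Of 10 folding genes 9 fell, and 9 adjusted over the list alone (camera adjusted p = 9.79e-15, adjusted p = 0.0942 with an estimated correlation), among them CRT3 by 3.27 ± 0.12 and PDIL1-2 by 2.15 ± 0.16. In senescence 5 of 8 genes fell, and 5 adjusted over the list alone (camera adjusted p = 0.000491, adjusted p = 0.255 with an estimated correlation), with SAG13 at -7.60 ± 0.77.

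Photosynthesis genes moved the other way, with 17 of 22 higher, and 20 adjusted over the list alone (camera adjusted p = 9.05e-07, adjusted p = 0.414 with an estimated correlation). LHCB3 rose by 0.92 ± 0.15 and LHCB2.2 by 0.89 ± 0.15. Of 6 cell expansion genes 5 rose, and 5 adjusted over the list alone (camera adjusted p = 0.000346, adjusted p = 0.141 with an estimated correlation), among them EXPA5 by 2.16 ± 0.32 and EXPA3 by 1.17 ± 0.16. Of 6 abscisic acid genes 5 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00825, adjusted p = 0.148 with an estimated correlation), with COR15A at 3.24 ± 0.55. Of 7 guard cell, epidermis and phloem markers 4 rose, and 6 adjusted over the list alone (camera adjusted p = 0.00336, adjusted p = 0.271 with an estimated correlation), with KAT1 at 1.89 ± 0.22. The jasmonate and ethylene list had 3 genes higher, 3 lower and 8 not past the test, with 4 and 3 adjusted over the list alone and no camera call (adjusted p = 0.454), and AOS rose by 1.85 ± 0.11 while HEL fell by 2.87 ± 0.20. In heat shock 2 of 7 genes rose and 2 fell, of 9 clock genes TOC1 fell, of 2 flowering markers 1 rose and of 8 reference genes 2 fell. Adjusted over the list alone these numbers were the same, with 1 reference gene more that rose. Of 10 cell cycle genes 0 passed edgeR, DESeq2, an unadjusted p of 0.05 or the adjustment over the list alone.

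Of 17358 genes, 4894 changed, 2086 higher and 2808 lower, with 810 and 1310 by at least 2-fold. The count was 2479 and 3247 without libraries 1 and 2 of the PBL19C3A line and 2504 without library 2 of the eds1 line. Of 69 named calls, 18 were lost without some single library. A further 574 genes that had risen in the PBL19C3A line against WT had no value in the eds1 line, and of these 517 were under 1 CPM (count scaled to library total) in both WT libraries. CRK4 (AT3G45860), a receptor-like kinase gene, had 2 counts in the eds1 line and a ratio of 18538 (95% counting interval 5131 to 153082). It was also called lower than in WT, and it lies in the stretch of chromosome 3 around EDS1 described below. This ratio therefore cannot be read as an immune effect alone.

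Against WT, the sid2 line was examined for what remains with the sid2 mutation. Some to most genes of every list in the salicylic acid, N-hydroxypipecolic acid, receptor and camalexin groups stood above WT, and 15 of 22 photosynthesis genes stood below. PBL19 rose by 6.41 ± 0.39 (edgeR adjusted p = 0.000229), and ICS1 had a log2 difference of -0.68 ± 0.23 (edgeR adjusted p = 0.082), lower in DESeq2 and adjusted over the list of 4 genes alone. EDS1 rose by 1.38 ± 0.28, a call lost without WT library 1 or sid2 library 2, at values from 1.06 to 1.79 over the fits without 1 library. FMO1 rose by 12.49 ± 0.81, from only 0 and 5 counts in WT libraries 1 and 2, and PR1 by 5.89 ± 0.53.

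Of 14 genes of salicylic acid synthesis and turnover 7 rose and 1 fell, with 8 and 2 adjusted over the list alone (camera adjusted p = 2.3e-07, adjusted p = 0.0942 with an estimated correlation), and PBS3 rose by 5.24 ± 0.36. Of 12 response genes 11 rose, and 11 adjusted over the list alone (camera adjusted p = 2.83e-09, adjusted p = 0.128 with an estimated correlation), among them PR2 by 4.80 ± 0.65 and PR5 by 3.30 ± 0.21. For N-hydroxypipecolic acid 6 of 8 rose, and 6 adjusted over the list alone (camera adjusted p = 5.5e-05, adjusted p = 0.109 with an estimated correlation), with ALD1 at 7.60 ± 0.69 (6.61 to 13.82 over the fits without 1 library). In the EDS1 hub 12 of 14 rose, and 13 adjusted over the list alone (camera adjusted p = 5.33e-10, adjusted p = 0.162 with an estimated correlation), with PAD4 at 3.59 ± 0.29. Of 21 pattern-triggered immunity genes 12 rose, and 17 adjusted over the list alone (camera adjusted p = 3.14e-09, adjusted p = 0.228 with an estimated correlation), among them NHL10 by 6.88 ± 0.60 and RLP23 by 3.70 ± 0.23. Of 15 camalexin genes 11 rose, and 14 adjusted over the list alone (camera adjusted p = 1.15e-14, adjusted p = 0.109 with an estimated correlation), among them CYP71A13 by 7.11 ± 0.58 and CYP71A12 by 6.25 ± 0.39. Of 18 jasmonate and ethylene genes 9 rose and 1 fell, with 13 and 1 adjusted over the list alone (camera adjusted p = 1.58e-07, adjusted p = 0.182 with an estimated correlation), among them PDF1.3 by 10.83 ± 1.1 and PDF1.2A by 9.86 ± 1.00. Of 11 folding genes 10 rose, and 11 adjusted over the list alone (camera adjusted p = 3.45e-08, adjusted p = 0.128 with an estimated correlation), with CRT3 at 1.19 ± 0.11. In senescence 5 of 8 rose, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.93e-05, adjusted p = 0.201 with an estimated correlation), and SAG13 rose by 7.53 ± 0.76. In heat shock 3 of 7 rose, and 3 adjusted over the list alone (camera adjusted p = 0.0286, adjusted p = 0.542 with an estimated correlation), a call that ended in fry (adjusted p = 0.156) and when all genes were ranked (adjusted p = 0.0571).

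Of 22 photosynthesis genes 15 fell, and 15 adjusted over the list alone (camera adjusted p = 8.01e-09, adjusted p = 0.36 with an estimated correlation). LHCB3 was lower by 0.81 ± 0.15, a call lost without WT library 1 or sid2 library 1, at values from -0.90 to -0.72 over the fits without 1 library. Of 6 cell expansion genes 4 fell, and 4 adjusted over the list alone (camera adjusted p = 4.98e-05, adjusted p = 0.136 with an estimated correlation), with EXPA11 at -1.41 ± 0.16. Of 7 guard cell, epidermis and phloem markers 3 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.306 with an estimated correlation), with KAT1 at -1.42 ± 0.21. In the abscisic acid, clock and reference lists 1 gene each rose. Adjusted over the list alone, 1 abscisic acid gene rose and 1 fell, 2 clock genes rose and 1 reference gene rose. None of 4 flowering markers passed edgeR, while 1 was higher in DESeq2, at an unadjusted p under 0.05 and adjusted over the list alone. None of 11 cell cycle genes passed edgeR, DESeq2 or the adjustment over the list alone, and 1 was lower at an unadjusted p under 0.05, but with the replicate block camera placed the cell cycle list lower (adjusted p = 0.0269). Of 17991 genes, 2906 changed, 2177 higher and 729 lower, with 1415 and 166 by at least 2-fold. The count was 1187 and 1846 without WT libraries 1 and 2 and 1299 without sid2 library 1, and 27 of 64 named calls were lost without some single library.

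The eds1 line was compared with WT to see what differs with the eds1 mutation. Few genes differed, and most of those lay on 1 chromosome. PBL19 had a log2 difference of 2.49 ± 0.33 (edgeR adjusted p = 0.0601), ICS1 one of -0.07 ± 0.22 (edgeR adjusted p = 1) and EDS1 one of -1.42 ± 0.29 (edgeR adjusted p = 0.393), none past the test. Of 17534 genes edgeR called 28, 6 higher and 22 lower, while 611 had an unadjusted p under 0.05 and DESeq2 called 92. The 611 are fewer than the share of 0.05 of the tested genes expected with no change. Of the 28, 22 have a place in the TAIR10.1 annotation and 21 of these lie on chromosome 3, against 3456 of 17206 tested genes (Fisher's exact test, two-sided, p = 3.89e-14).

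Among the lower genes, AT3G47680 was at least 813-fold lower, AT3G43740 at least 551-fold lower and the steroid dehydrogenase gene HSD2 (AT3G47350) at least 544-fold lower, since the eds1 line had 0 counts for each. The downy mildew resistance gene RPP13 (AT3G46530) fell by 2.11 ± 0.16, from 24.3 ± 5.37 to 5.79 ± 0.202 FPKM, and the phosphate transporter gene PHT4;3 (AT3G46980) by 2.05 ± 0.13. CRK4 was lower by a ratio of 631 (95% counting interval 174 to 5215). Among the higher genes, AT3G44070 was at least 395-fold higher, and MRD1 (AT1G53480), the gene of the 22 on another chromosome, was higher by a ratio of 505 (95% counting interval 172 to 2450.3). Of the 28 calls, 10 were lost without some single library, and 17 genes were called when the libraries of these 2 genotypes were fitted alone. In none of the lists did edgeR call a gene. Adjusted over the list alone, PBL19 was higher and EDS1 lower, 2 heat shock genes were higher, and 1 gene each was lower in salicylic acid synthesis, the EDS1 hub and pattern-triggered immunity. DESeq2 called the same numbers in these lists. The lower gene of the EDS1 hub is EDS1 itself, so it is counted in both places. At an unadjusted p under 0.05, 5 jasmonate and ethylene genes and 4 heat shock genes were higher. Camera placed the jasmonate and ethylene list higher (camera adjusted p = 6.25e-10, adjusted p = 0.141 with an estimated correlation), heat shock higher (camera adjusted p = 6.18e-07, adjusted p = 0.225 with an estimated correlation), pattern-triggered immunity higher (camera adjusted p = 0.00451, adjusted p = 0.524 with an estimated correlation), camalexin higher (camera adjusted p = 0.0455, adjusted p = 0.434 with an estimated correlation) and photosynthesis lower (camera adjusted p = 0.000235, adjusted p = 0.554 with an estimated correlation). The camalexin call ended with the replicate block (adjusted p = 0.0538) and when all genes were ranked (adjusted p = 0.0535). With the block, camera also placed the abscisic acid list higher (adjusted p = 0.0287). Fry called 0 of these 5 lists. On the second principal component, eds1 library 1 lay at -36.2 and library 2 at 2.51, beside 6.44 and 23.3 in WT. WRKY33 (AT2G38470), of the pattern-triggered immunity list, stood at 134 and 20.7 FPKM in eds1 libraries 1 and 2, beside 14.5 and 34.2 in WT. Other members were above WT in both, such as PEPR1 (AT1G73080) at 13.4 and 11.2, beside 8.15 and 9.71. These list calls may therefore rest in part on eds1 library 1.

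**Figure D3:**
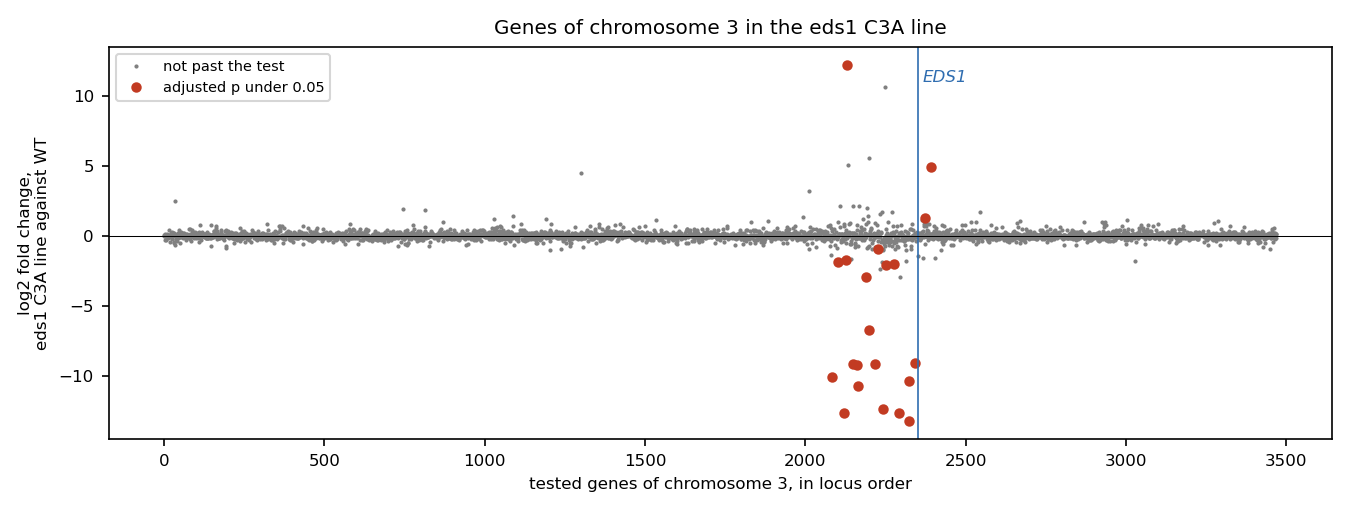
Log2 fold change of the eds1 line over WT for tested genes of chromosome 3 in the order of their locus numbers, with called genes in red and EDS1 marked. Of the 28 calls, 20 lie among the 290 tested genes from TES to AT3G48640, a stretch that holds EDS1. Its ends were set by called genes.

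The sid2 and eds1 lines were then compared directly. Part of the genes of each immune list were lower in the eds1 line than in the sid2 line, as counted below, and PBL19 was lower by 3.93 ± 0.35 (edgeR adjusted p = 0.000886). EDS1 fell by 2.80 ± 0.30 (edgeR adjusted p = 0.00214), and ICS1 had a log2 difference of 0.61 ± 0.23 (edgeR adjusted p = 0.144), higher adjusted over the list alone but not called by DESeq2. CYP71A12 fell by 5.43 ± 0.36, from 62.9 ± 15.6 to 1.43 ± 0.405 FPKM, and SAG13 by 7.89 ± 0.78.

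In salicylic acid synthesis 5 of 11 genes fell, with 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 3.64e-08, adjusted p = 0.0942 with an estimated correlation), and PBS3 fell by 6.77 ± 0.39. Of 9 response genes 4 fell, with 8 adjusted over the list alone (camera adjusted p = 4.11e-09, adjusted p = 0.141 with an estimated correlation), among them PR2 by 6.62 ± 0.72. For N-hydroxypipecolic acid 3 of 5 fell, and 3 adjusted over the list alone (camera adjusted p = 1.88e-06, adjusted p = 0.0942 with an estimated correlation), with SARD4 at -3.45 ± 0.22. In the EDS1 hub 8 of 13 fell, EDS1 itself among them, and 11 adjusted over the list alone (camera adjusted p = 4.87e-10, adjusted p = 0.182 with an estimated correlation), with PAD4 at -3.76 ± 0.29. In pattern-triggered immunity 7 of 18 fell, and 8 adjusted over the list alone (camera adjusted p = 3.03e-06, adjusted p = 0.307 with an estimated correlation), with RLP23 at -5.08 ± 0.25. In the camalexin list 8 of 12 fell, and 8 adjusted over the list alone (camera adjusted p = 4.76e-13, adjusted p = 0.109 with an estimated correlation), with CYP79B2 (AT4G39950) at -3.03 ± 0.30. In jasmonate and ethylene 3 of 14 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00809, adjusted p = 0.405 with an estimated correlation, and 0.113 when all genes were ranked, which ends the call), and HEL fell by 3.64 ± 0.21 and ORA59 by 2.27 ± 0.26. Of 10 folding genes 7 fell, and 9 adjusted over the list alone (camera adjusted p = 1.43e-08, adjusted p = 0.128 with an estimated correlation), with PDIL1-2 at -1.67 ± 0.15. In senescence 4 of 8 fell, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.67e-05, adjusted p = 0.187 with an estimated correlation).

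Photosynthesis genes were higher in the eds1 line for 4 of 22, and 13 adjusted over the list alone (camera adjusted p = 2.38e-05, adjusted p = 0.497 with an estimated correlation). Of 6 cell expansion genes 3 rose, and 6 adjusted over the list alone (camera adjusted p = 1.86e-05, adjusted p = 0.128 with an estimated correlation), with EXPA11 at 1.22 ± 0.16. Of 7 guard cell, epidermis and phloem markers 2 rose, and 2 adjusted over the list alone (camera adjusted p = 0.0275, adjusted p = 0.378 with an estimated correlation). Fry made no call for the photosynthesis, guard cell and jasmonate lists (adjusted p = 0.0642, 0.0561 and 0.0941). In heat shock 1 gene rose and 1 fell, with 1 and 2 adjusted over the list alone. The abscisic acid, clock, cell cycle, flowering and reference lists had 0 calls in edgeR and adjusted over the list alone. At an unadjusted p under 0.05 they held 1, 2, 0, 0 and 1 genes, and DESeq2 called 1, 1, 0, 0 and 1. Of 17397 genes, 1636 changed, 415 higher and 1221 lower, with 118 and 713 by at least 2-fold. The count was 617 and 985 without libraries 1 and 2 of the sid2 line and 629 without eds1 library 2. It was 848 when these 2 genotypes were fitted alone, 2574 in DESeq2 and 2471 with the replicate block.

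The last question was how much of the difference between the PBL19C3A line and WT was absent from the sid2 and eds1 lines. Among genes that rose in the PBL19C3A line and have a value in the other line, 61.5% of 3691 lay within 2-fold of WT in the sid2 line and 97.3% of 3280 in the eds1 line. In the PBL19C3A line itself these shares were 46.4% and 52.3%. Among the 2682 genes that fell, 91.1% lay within 2-fold of WT in the sid2 line and 99.4% in the eds1 line, against 65.7% in the PBL19C3A line. Of 1130 genes raised at least 4-fold, 989 have a value in the sid2 line, of which 4.25% lay within 2-fold of WT, and 605 have one in the eds1 line, of which 88.4% did, so these shares rest on different genes. Of 118 genes lowered as much, all with a value, it was 33.9% and 93.2%. In the sid2 line it was 29.8% of 1977 genes raised at least 2-fold, a limit chosen after seeing the data. The 163 raised genes without a value in the sid2 line and the 574 in the eds1 line were low there and in WT. Leaving them out may make the shares within 2-fold of WT too low. The same holds for the shares of raised genes that were lower than in the PBL19C3A line. By the direct tests, 347 of the raised genes (9.40%) were lower in the sid2 line than in the PBL19C3A line, and 2593 (79.1%) were lower in the eds1 line. Without libraries 1 and 2 of the PBL19C3A line the share for the sid2 line was 1.27% and 0.743%, and without those of the sid2 line it was 1.21% and 1.19%. The share for the eds1 line was 50.3% without eds1 library 2. Still higher than in WT were 1990 raised genes in the sid2 line (53.9%), against 440.0 for independent lists, and 2 in the eds1 line, against 0.567. In 50 simulations without any effect these comparisons made almost no calls and shared 0, which says nothing about what the shared WT libraries add. In 20 simulations that gave the changes of the sid2 line to random genes of similar level, the shared raised genes numbered between 448 and 514, with a mean of 480.2 against 383.48 for independent lists. Part of the excess over independent lists may therefore come from the WT libraries that both comparisons use, which are too few to split. The slope of log2 change against WT on that in the PBL19C3A line was 0.741 over 6314 genes for the sid2 line and 0.084 over 5958 genes for the eds1 line. The slope for the eds1 line was 0.166 without WT library 2, 0.142 without eds1 library 2 and 0.00824 without eds1 library 1. Because both axes share the WT libraries, the slope lies above 0 without any kept change, at 0.0348 in 20 simulations of an unchanged eds1 line (0.03 to 0.0387) and at 0.0569 with the changes of the sid2 line on random genes. The slope of 0.084 lies above these values, but without 1 library it fell as low as 0.00824, so whether the eds1 line keeps a part of the change stays open. Across 17327 genes, which are no independent replicates, the correlation of these changes was 0.881 for the sid2 line and 0.242 for the eds1 line. In simulations without any effect in any line, the shared WT libraries gave a correlation of 0.499. There, noise made all of the variance, while here the PBL19C3A line has changes of its own. The value of 0.499 is therefore no baseline for these correlations, and none was simulated with the changes of the PBL19C3A line kept. The covariance was 0.578 for the sid2 line, against 0.037 in the simulations, and 0.0802 for the eds1 line, against 0.0371.

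**Figure D4:**
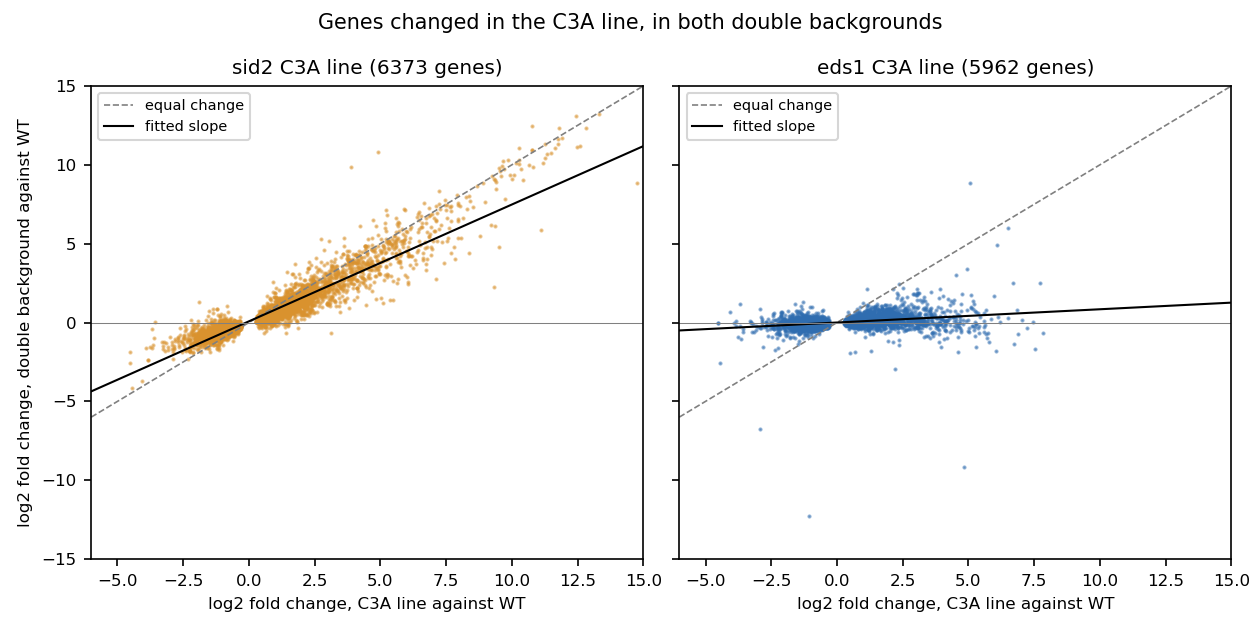
Log2 fold change against WT in the sid2 line and in the eds1 line (vertical axes) against that in the PBL19C3A line (horizontal axis), with a point per gene called in the PBL19C3A line. The dashed line marks equal change, and the black lines are the slopes of 0.741 and 0.084 fitted to genes with more than 3 counts in each group.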

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

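The comparison of the eds1 line with the sid2 line was planned, and the tests that weigh explanations here were chosen only after the results were seen. Both lines carry the same construct, though the titles do not say whether as the same insertion. Their levels differed in a direct test for 1636 genes (edgeR, Benjamini-Hochberg, adjusted p under 0.05). This count rose to 2471 with the replicate block and fell without single libraries of the sid2 or the eds1 line. PBL19 itself differed between them, with a log2 fold change of -3.93 of the eds1 line over the sid2 line, and so did EDS1, with -2.80. These stand here because the lines were tested against each other directly and differed, and what part of this the mutations cause was not tested.

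Most genes that edgeR called between the eds1 line and WT lie close together. Of the calls with a place in the annotation, 95.5% are on chromosome 3, where 20.1% of the placed tested genes are. For these calls this speaks against a response spread across the genome. The 92 calls of DESeq2 were not placed, so a weaker response across the genome stays open. The 611 of 17534 genes at an unadjusted p under 0.05 are fewer than the share of 0.05 expected with no change. That count is therefore no sign of such a response. The eds1 line also differs from WT by the pbl19 mutation and the transgene. Of the 28 calls, 25 have a value against the PBL19C3A line and 24 against the sid2 line. There, 24 and 23 of them were called the same way, so these genes also enter those comparisons. Too few reads cannot account for the 12 calls at 0 counts in the eds1 line, since the WT level would have given at least 134 counts in each. A call at 0 counts already needs a high WT level, so this follows largely from how these genes were picked. A candidate explanation is a linked stretch of chromosome 3 around EDS1 that came from another parent when the eds1 mutation was crossed in. From TES to AT3G48640 lie 290 tested genes and 20 of the 28 calls. The ends of this stretch were set by called genes, so this count describes the calls and does not test the explanation. The parentage of the mutant, the sequence of its reads and the call of MRD1 outside the chromosome were not tested, and regulation of that stretch by EDS1 stays open as well.

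PBL19 transcript was lower in the eds1 line than in the PBL19C3A line, and lower in the sid2 line in DESeq2 and adjusted over the list of 4 genotype genes alone, but not in edgeR over all genes. If a lower transgene level alone lowered every change of the sid2 line by the same share, all lists would keep the same part of their change. The median share of the log2 change kept was 55.6% in endoplasmic reticulum folding, 57.5% in salicylic acid response (12 of 16 raised genes have a value) and 63.7% in the EDS1 hub. It was 67.6% in pattern-triggered immunity, 67.8% in salicylic acid synthesis, 94.6% in senescence and 95.3% in N-hydroxypipecolic acid. In camalexin it was 97.8%, and in jasmonate and ethylene 140%. A rank permutation test over 93 genes of the 9 lists gave p = 1e-05, the smallest value 100000 resamples give. It shuffles single genes, which are no independent replicates where a list moves together. The salicylic acid synthesis list also holds ICS1, the gene mutated in the sid2 line. The medians differed between lists, but this p cannot decide whether they differ beyond the spread between plants. A lower level that acts by unequal shares stays open as well. In the eds1 line an effect of EDS1 on the immune genes and a lower transgene level cannot be told apart, because 1 gene off chromosome 3 that is raised in both lines, MRD1, is too little to set lists against each other. Whether the PBL19 promoter itself responds to the immune state, so that the lower transcript may follow from the weaker response, was not tested. Nor was it tested whether the lines hold the same insertion of the transgene.

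Clock genes differed between the replicate numbers. Of 9 clock genes, 8 moved in 1 direction between libraries 1 and 2 in all 4 genotypes, against 25.7% of 17327 genes (Fisher's exact test, two-sided, p = 0.000131). CCA1, LHY and RVE8 were lower and TOC1, GI, PRR9, PRR7 and LUX higher in the libraries numbered 1. The test counts single genes, which are no independent replicates where clock genes move together, and it was chosen after the pattern was seen. Its p therefore cannot say how rare such a pattern is. Of 1130 genes raised at least 4-fold in the PBL19C3A line, 603 have a value in all genotypes, and their median log2 difference of library 1 from library 2 was -0.398 in WT, 0.0939 in the PBL19C3A line, 0.0919 in the sid2 line and 0.29 in the eds1 line. With a mean of 0.0195 (95% interval between the 4 genotypes -0.447 to 0.486), 1 library against 1 per genotype is too few to decide on a further advanced immune response in the libraries numbered 1, which stays open. A different time of day at harvest for the replicate numbers could account for the clock genes, but the labels name no harvest time, and other causes that follow the numbering stay open.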

How the results depend on the processing

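The fits of only genes in all 3 tables, the list test over all genes of a comparison and the share lost among calls of at least 2-fold were chosen after seeing the data, and the other alternatives before the data were examined. No result reversed. Of the alternatives for named genes, 4256 kept direction and side of the threshold, 480 fell short of it and 7 newly passed, and of those for lists 322, 78 and 8. DESeq2 size factors, the filter at 5 FPKM and genes in all 3 tables left all 6 counts within 1.5 times their value. The absent low-count filter moved nothing, because it removed no gene. With a minimum of 2-fold, which keeps fewer genes by construction, the counts were 3059 for the PBL19C3A line against WT, 264 for the sid2 and 2120 for the eds1 line against the PBL19C3A line, 1581 for the sid2 line against WT and 831 for the eds1 against the sid2 line. The DESeq2 Wald test gave 1378 for the sid2 against the PBL19C3A line, 92 for the eds1 line against WT and 2574 for the eds1 against the sid2 line, and the cause was not tested. Fits of only the 2 groups compared, with fewer samples by construction, gave 17 for the eds1 line against WT and 848 for the eds1 against the sid2 line. Camera called 62 pairs of a list and a comparison, and 0 with an estimated correlation (33 at an unadjusted p under 0.05), 53 by fry, and 61 when all genes of a comparison were ranked. The version with an estimated correlation has little power with 2 libraries per genotype, so its 0 calls cannot decide against a list.

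With the replicate block, the counts were 924 for the sid2 against the PBL19C3A line and 2471 for the eds1 against the sid2 line, and 64 list calls. All 469 and all 1636 calls of these comparisons were among them. Of the list calls, camalexin in the eds1 line against WT was lost, and abscisic acid in the PBL19C3A and the eds1 line against WT and the cell cycle in the sid2 line against WT were gained. Of the named genes, EARLI1 (AT4G12480) lost its call in the eds1 against the PBL19C3A line. The block changed no other list call or call of a named gene, and no other count by more than 1.5 times.

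Without 1 library in turn, where the lone library left in a group is assumed to vary like the other groups, the counts ranged from 3729 to 6287 for the PBL19C3A line against WT, from 24 to 390 for the sid2 and from 2479 to 4543 for the eds1 line against the PBL19C3A line, from 1187 to 2843 for the sid2 and from 22 to 32 for the eds1 line against WT, and from 617 to 1398 for the eds1 against the sid2 line. These fits hold fewer samples by construction. Calls past the test in every fit without 1 of the compared libraries numbered 3086, 19, 1987, 989, 18 and 485 in that order.

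Of the genes raised in the PBL19C3A line, the share within 2-fold of WT in the sid2 line was 4.25% for calls of at least 4-fold, 29.8% for calls of at least 2-fold, 43.3% with a limit of 1.5-fold, and 48.1 to 63.6% without 1 library. In the eds1 line these were 88.4%, 94.5%, 91.7%, and 92.1 to 97.6%. For lowered genes they were 33.9%, 75.0%, 66.3%, and 83.2 to 92.2% in the sid2 line, and 93.2%, 98.5%, 97.0%, and 98.3 to 99.6% in the eds1 line. The tighter limits and larger folds lower these shares by construction. Raised genes without a value in a line are left out of its shares. The share of raised genes that were lower than in the PBL19C3A line was 17.0% for calls of at least 4-fold and 14.3% for calls of at least 2-fold in the sid2 line, with 0.743 to 11.4% without 1 library. It was 92.7% for calls of at least 4-fold in the eds1 line, with 50.3 to 93.2% without 1 library. The slope was 0.692 to 0.794 in the sid2 line and 0.00824 to 0.166 in the eds1 line without 1 library.

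Other pseudocounts and quantile scaling of FPKM were not run because counts were used, nor the authors' own significance values, which the tables used here do not hold, nor unmatched random lists and list means, which were meant for 1 value per genotype. Scaling moved the median log2 change of a comparison by between -0.00989 and 0.00958. With 2 libraries per genotype at this depth, 60% of simulated 2-fold changes were called, among genes above a level limit and with the same variation for all.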

Other observations

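The gene families and the genes of the sid2 line in this part were chosen after their values were seen, with the calls of the planned edgeR comparisons. In the PBL19C3A line against WT, where 36.2% of all genes changed, 10 families differed in how many members were called. Of 57 measured WRKY transcription factor genes 43 rose and 1 fell, of 51 NAC transcription factor genes 31 rose, of 38 cysteine-rich receptor-like kinase (CRK) genes 28 rose and 2 fell, and of 49 receptor-like protein (RLP) genes 33 rose and 2 fell. In growth-related families, 26 of 41 SAUR genes were lower and 8 higher, and 10 of 14 alpha-expansin genes were lower. A smaller share passed in the other 4 families, with 6 higher and 4 lower of 21 GSTU genes (glutathione transferases), 8 and 1 of 22 PUB genes (ubiquitin ligases), 1 and 5 of 16 BHLH genes (transcription factors) and 1 and 1 of 10 JAZ genes (jasmonate repressors). In the sid2 line against the PBL19C3A line, 9 of 37 CRK genes and 10 of 46 RLP genes fell, with 1 and 0 higher, while 3 of 51 WRKY and 3 of 49 NAC genes fell and 0 of 40 SAUR genes passed edgeR. In the eds1 line against the PBL19C3A line, 20 of 40 WRKY, 16 of 26 CRK, 20 of 36 RLP and 17 of 44 NAC genes fell, with 0, 2, 1 and 1 higher, and 21 of 40 SAUR and 11 of 14 alpha-expansin genes rose, with 5 and 0 lower. In the sid2 line against the PBL19C3A line, 3 of 20 GSTU genes rose and 0 fell, and 1 of 22 PUB genes fell. There 0 of 14 alpha-expansin, 14 BHLH and 10 JAZ genes passed. In the eds1 line against the PBL19C3A line, 4 of 15 GSTU genes rose and 2 fell, and 2 of 21 PUB genes rose and 6 fell. Of 15 BHLH genes 6 rose, and of 10 JAZ genes 2 rose, with 0 lower. No family was tested as a set.

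In the sid2 line, 23 genes were higher and 6 lower than in both the PBL19C3A line and WT. The oxygenase gene DIN11 (AT3G49620) stood at 4.29 FPKM in WT, 3.95 in the PBL19C3A line and 86.4 in the sid2 line, and the acyltransferase gene AACT1 (AT5G61160) at 1.68, 1.69 and 28.1. The jasmonate-responsive gene JRG21 (AT3G55970) was higher by 2.56 than in the PBL19C3A line and by 5.30 than in WT (log2), and NATA1 (AT2G39030), an acetyltransferase gene induced by jasmonate, by 1.96 and 7.15. The squalene epoxidase family genes SQP1 (AT5G24150) and SQE6 (AT5G24160) were higher by 1.90 and 1.13 than in the PBL19C3A line. The germin-like gene GER1 (AT1G72610) was lower, at 475 FPKM beside 783 in WT and 1005 in the PBL19C3A line. Against the PBL19C3A line 469 genes were called at all, and 34, 24, 61 and 56 without libraries 1 and 2 of the PBL19C3A line and of the sid2 line. None of these 29 genes kept the call against the PBL19C3A line in every fit without 1 compared library, while 17 kept the call against WT.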
